A study of Mus musculus with 12 samples.

How the data were processed

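Expression was measured on Agilent mouse arrays of design 014868 in E14 embryonic stem cells after knockdown of p400 or Tip60 or control treatment with EGFP esiRNA, for 72 hr at 0.33 ng/µl per the labels. There were 4 two-colour arrays of p400 knockdown against EGFP, 4 single-colour arrays of Tip60 knockdown and 4 of EGFP control. Per the file headers, the scans were read with Agilent Feature Extraction 9.5.1.1, which gave the mean, median and background intensity of each spot. It also gave a processed signal, an intensity after background subtraction and detrending within the array, and on the two-colour arrays after linear and LOWESS dye normalization. The deposited LogRatio column of the two-colour arrays holds the log10 ratio of red over green processed signal. The deposited series matrix holds log2 values whose normalization steps are not stated. Its p400 columns are log2 ratios of knockdown over EGFP with medians from 0 to 0.01, whose r with LogRatio was 0.815, -0.815, 0.823 and -0.797 on replicates 1 to 4, following the dye order in the labels. Its single-colour columns, with medians from 7.26 to 7.27, follow the log2 median signal of the array (r from 0.999 to 1.00), as after quantile normalization. Probe positions are on build mm7 per the file headers.

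For the p400 arrays, mean signal and median background were corrected with normexp (offset 50) and normalized within each array by loess with control spots at weight 0. A limma model was fitted with the knockdown effect, coded by dye, and a dye term. For the single-colour arrays, the log2 processed signal was set relative to the array's 75th percentile, and Tip60 replicates 1, 2 and 4 were compared with EGFP replicates 1 to 4 with lmFit and eBayes. Tip60 replicate 3 was left out, as the submitters state they did, and entered in an alternative. The 1639 control spots per array and spots flagged as outliers were left out, and replicate spots of a probe were averaged. A probe was tested where it was well above background on at least 3 arrays of either RNA, and a gene was represented by its brightest tested probe. A gene dim in EGFP RNA was thus tested only where bright in knockdown RNA, which favours rises over falls among such genes. Several tested probes existed for 6520 genes in the p400 fit and 5950 in the Tip60 fit. Of these, 127 and 24 had probes called in opposite directions. Each of the 41174 probes was named by its accession (22951), its symbol (6659) or a synonym (3109) in the reference genes, or kept the name in the file (8455). This left 27670 names. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and all limma and camera tests are two-sided.

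Gene lists were tested with camera (preset correlation 0.01, adjusted over the 21 lists), with camera using an estimated correlation, and with fry. The lists were the Tip60-p400 complex, pluripotency, neural ectoderm, mesoderm, endoderm, trophectoderm, feeder fibroblasts, germ cells, 2-cell-like genes, Hox genes, imprinted genes, mitosis, DNA replication, p53 targets, ribosome biogenesis, interferon response, stress response, epithelial junctions, cholesterol synthesis, glycolysis and hypoxia, and housekeeping genes. Of their 449 genes, 440 were on the array. List medians did not change when genes not well above background in a group were put at their bound. Hox genes had 2 such members in p400 and 1 in Tip60 knockdown, and endoderm genes 1 in each. Neural ectoderm genes had 1 in p400 and interferon response genes 1 in Tip60 knockdown. Elsewhere there were none, so those medians could not change. The difference between the p400 and Tip60 effects was divided by the root of the summed squared moderated standard errors, with Welch-Satterthwaite degrees of freedom. The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says that a test or an alternative was chosen later. The rule took Ep400, Kat5, Pou5f1, Sox2, Nanog, Klf4 and Zfp42, and the 10 largest rises and 10 largest falls past the threshold with a gene symbol and the same sign on all arrays (p400) or groups that do not overlap (Tip60). It also took up to 2 rises and 2 falls per list, of which some were left out for length, and the 5 largest differences each way. The 5 largest shared rises and falls were taken by the smaller of the 2 absolute log2 fold changes.

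The steps after normalization were tested on simulated data with known changes. In the p400 design (18691 genes), 62.7% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 4.47% of calls were false. In the Tip60 design (16949 genes) the shares were 64.2%, 80.6% and 90.9%, with 8.67% of calls false. In the test of the difference (16398 genes) they were 55.2%, 80.3% and 93.8%, with 16.7% of calls false, so this test is liberal. With the smaller degrees of freedom of the 2 fits they were 10.4%, 59.1% and 90.6%, with 0.952% false. In both designs camera called the raised list and 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this does not test camera on lists of correlated genes.

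Alternatives for p400 were Agilent's processed signals with loess, LogRatio as deposited, median centring in place of loess, scaling or Aquantile between arrays, the series matrix, other filters on dim probes, no dye term and, in the comparison of both knockdowns and the test by control level only, normexp with the offset at 0. Those for Tip60 were replicate 3 included with and without array weights, normexp, quantile or median normalization, the series matrix, other filters, the slide as a block and within each slide, and the replicate number as a block. Both fits were also run with the mean of a gene's probes, robust empirical Bayes with trend, a fold change of at least 1.5, and without each replicate in turn. The gene lists were not run with the mean of probes, robust empirical Bayes or the fold cut. Their counts of alternatives include the estimated correlation and fry. The work used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.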

Results

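RNA levels were measured on Agilent mouse expression arrays in E14 cells, a mouse embryonic stem cell line. The cells had been treated for 72 hr with 0.33 ng/µl esiRNA, a pool of short interfering RNAs cut by an enzyme from long double-stranded RNA. The esiRNA was directed against p400 (gene Ep400), a chromatin remodelling ATPase, or against Tip60 (gene Kat5, called Htatip on the array), a histone acetyltransferase of the same complex. Control cells received esiRNA against EGFP, a reporter gene. The p400 knockdown was measured on 4 two-colour arrays of slide 1, each with p400 knockdown RNA in one dye and EGFP control RNA in the other. The p400 RNA carried Cy5 in replicates 1 and 3 and Cy3 in replicates 2 and 4. The Tip60 knockdown was measured on 4 single-colour arrays and set against 4 single-colour EGFP arrays, on slides 2 and 3, each of which held both groups. The design calls the replicates biological, and it states that Tip60 replicate 3 was left out of the submitters' comparison because its intensity profile was an outlier. Of 43379 spots per array, 27598 to 30752 were well above background in a channel of the p400 arrays, and 25073 to 30107 on the single-colour arrays other than Tip60 replicate 3, which had 22188. The number of arrays limits the precision of every value.

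The targeted genes were examined first in every sample. In p400 knockdown, the Ep400 probe at chromosome 5, 109831052 to 109831111 (build mm7), gave log2 ratios of knockdown over EGFP of -0.65, -0.77, -0.24 and -0.67 on replicates 1 to 4. Of the 3 other Ep400 probes, one averaged -0.72 but stood at 0.06 on replicate 1, one averaged 0.22, and one was not well above background in EGFP RNA on any of the 4 arrays. The labels do not give the region that the esiRNA targets, so whether a probe overlaps it could not be checked. In Tip60 knockdown, the Kat5 probe at chromosome 19, 5498325 to 5498465, had log2 levels, relative to the array's 75th percentile, of -0.19, -0.30 and -0.27 in replicates 1, 2 and 4. Its levels in EGFP replicates 1 to 4 were 1.16, 1.15, 1.22 and 1.39, and Tip60 replicate 3, which entered the comparison in alternatives only, stood at 0.04.

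**Figure D1:**
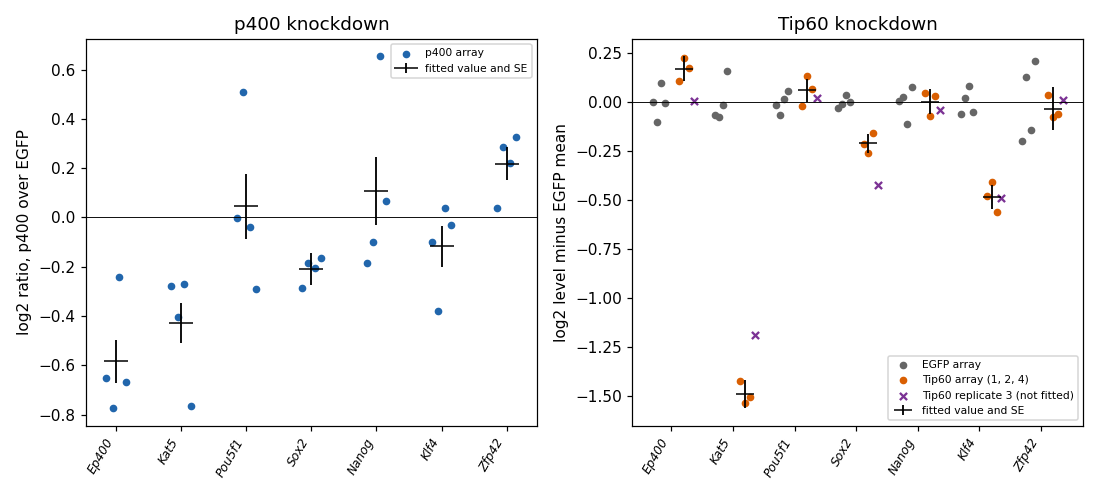
Ep400, Kat5 and 5 pluripotency genes, with the log2 ratio of p400 knockdown over EGFP (left) and the log2 level minus the EGFP mean (right) on the vertical axes. Points are arrays, the cross is Tip60 replicate 3, and black ticks are fitted values with standard errors, where Ep400 stands at -0.58 in p400 knockdown and Kat5 at -1.49 in Tip60 knockdown.

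The first comparison asks which genes depend on p400 in embryonic stem cells. Knockdown of p400 raised all 7 measured genes of a list that marks the 2-cell embryo: Zfp352, a zinc finger gene transcribed at that stage, rose 22.9-fold (log2 4.52 ± 0.17 SE, n = 4 arrays), and Zscan4c, a marker of the 2-cell-like state, rose 20.7-fold (4.37 ± 0.29). Hspa1a, the inducible heat shock protein Hsp70, rose 17.1-fold (4.10 ± 0.10), and Arg2, the mitochondrial arginase, rose 13.7-fold (3.78 ± 0.20). By the rule for named genes, the deepest falls were in Lrrc34 (-1.55 ± 0.08) and in Ldhb, a subunit of lactate dehydrogenase (-1.55 ± 0.07). Of 25 germ cell genes 17 rose, among them Dazl, an RNA-binding protein (2.07), and of 20 endoderm genes 11 rose, among them Gata6, a transcription factor of the primitive endoderm (1.26). Camera called both lists with a preset correlation (adjusted p = 0.000386 and 0.00228) and neither with an estimated correlation (adjusted p = 0.536 for both). Ep400 itself fell by 0.58 on the log2 scale with the first of its probes named (± 0.09, limma adjusted p = 0.00556), and Kat5 fell by 0.43 (± 0.08, adjusted p = 0.0109).

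Of 18691 genes tested with limma, 6577 passed an adjusted p of 0.05, 3766 higher and 2811 lower in p400 knockdown, against 8723 with an unadjusted p under that value. Most changes were small: 532 genes were at least 2-fold higher and 26 at least 2-fold lower, and 54 were at least 8-fold higher. The other large rises were in Krtap4-13, a keratin-associated protein of hair (4.40 ± 0.15), in Tcstv3 and Usp17la, of multicopy families of the 2-cell stage (4.29 ± 0.23 and 4.20 ± 0.22), and in Clec10a, a lectin of macrophages (4.03 ± 0.22). Csf2rb, a subunit of cytokine receptors (3.77 ± 0.19), and Sp110, a nuclear body protein (3.68 ± 0.14), followed. Over the alternatives Csf2rb ran from 1.87 to 4.11. The other large falls were in Mgarp (-1.43), Efs (-1.33), the transcription factor Klf15 (-1.29), St8sia1, which makes the ganglioside GD3 (-1.25), and Zfp773 (-1.24). The homeobox gene Nkx6-3 (-1.22), the long non-coding RNA Lockd (-1.20) and Sycp3, a part of the meiotic synaptonemal complex (-1.16), also fell. Adjusted p for these 20 rises and falls lay between 0.000114 and 0.00454.

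**Figure D2:**
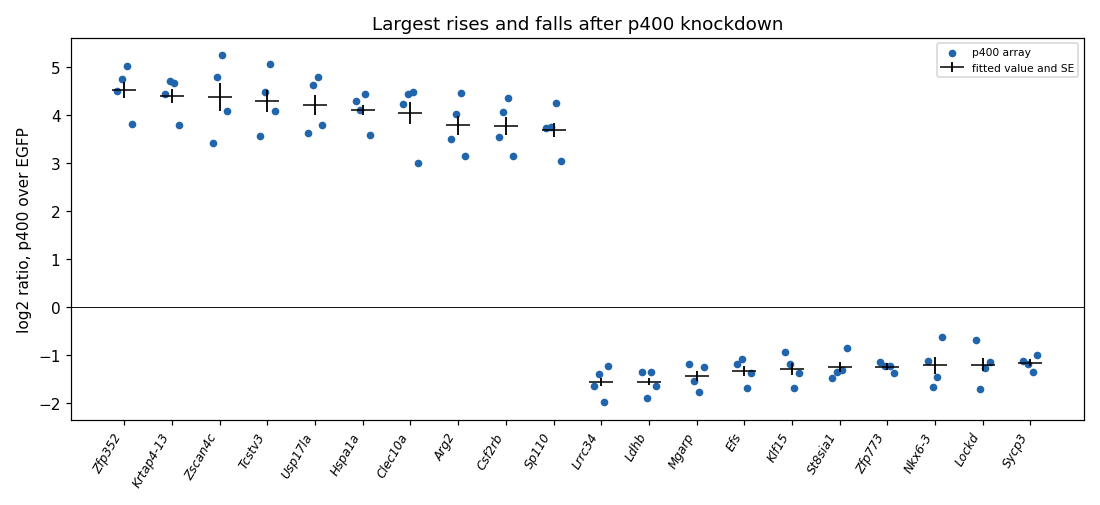
The 10 genes with the largest rise and the 10 with the largest fall in p400 knockdown, with the log2 ratio of knockdown over EGFP on the vertical axis. Points are the 4 arrays and black ticks the fitted values with standard errors, from 4.52 for Zfp352 to -1.55 for Lrrc34.

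Camera called 8 of 21 lists in p400 knockdown with the preset correlation, and none with an estimated correlation, which gave an adjusted p = 0.536 for each of the 8 and no unadjusted p under 0.05. Fry called none either (lowest adjusted p = 0.0589). The list of 2-cell-like genes had 7 measured members, and all 7 rose (7 adjusted over the list alone, median log2 4.20, camera adjusted p = 6.75e-07 with the preset correlation). Of 25 germ cell genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone, median 0.46, camera adjusted p = 0.000386). Dazl stood at 2.07 and Stra8, which acts at the entry into meiosis, at 1.38, while Sycp3 fell. Of 20 endoderm genes, 11 rose and none fell (12 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 0.00228). Gata6 stood at 1.26 and Sox17, a transcription factor of endoderm, at 1.01. Of 17 trophectoderm genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.00359), including the keratins Krt18 and Krt8 at 0.90 each. Of 21 Hox genes, which pattern the body axis, 5 rose and none fell (5 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.0205). Over all 18691 genes tested, 3766 were called higher. The array held 37 Hox genes, and the others were too dim to test. Genes dim in EGFP RNA entered only where bright in p400 knockdown, which favours rises. Hoxd13 stood at 1.37 and Hoxb2 at 1.18. Over the alternatives they ran from 1.05 to 2.52 and from 0.89 to 3.20. Of 20 interferon response genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.0350). Ddx58, a sensor of viral RNA, stood at 0.73 and Bst2, a membrane protein that holds back viruses, at -0.67. This list lost its call under 5 of 15 alternatives, and Hox genes under 3 of 15.

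Glycolysis and hypoxia genes were lower as a list in p400 knockdown: 9 of 20 fell and 2 rose (9 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 0.00273, and adjusted p = 0.536 with an estimated correlation). Eno1, a glycolytic enzyme, stood at -1.01, though at 0.01 on replicate 2, and Bnip3, a mitochondrial protein induced by hypoxia, stood at -0.81. Of 20 mitosis genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.0350, and adjusted p = 0.536 with an estimated correlation). The proliferation marker Mki67 stood at -0.50 and the mitotic kinase Aurkb at -0.41, whose call was lost under 4 of 15 alternatives. The mitosis list lost its call under 8 of 15 alternatives, and the other called lists under 2 of 15 each, apart from interferon response and Hox genes. Over the 14 settings run for list medians, the median ran from 3.84 to 4.65 for the 2-cell-like list. For germ cell genes it ran from 0.35 to 0.67, for endoderm genes 0.30 to 0.64 and for trophectoderm genes 0.30 to 0.89. It ran from 0.06 to 0.75 for Hox, 0.11 to 0.39 for interferon response, -0.54 to -0.18 for glycolysis and -0.48 to -0.16 for mitosis genes.

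Of the 5 pluripotency genes named in advance, Sox2 alone passed the threshold in p400 knockdown. Pou5f1 stood at 0.04 ± 0.13 (limma adjusted p = 0.818), Nanog at 0.11 ± 0.14 (adjusted p = 0.576), Klf4 at -0.12 ± 0.08 (adjusted p = 0.310) and Zfp42, also called Rex1, at 0.22 ± 0.07 (adjusted p = 0.0507). Sox2 fell by 0.21 (± 0.06, adjusted p = 0.0479), and missed the threshold under 8 of 15 alternatives. Of 27 pluripotency genes, 4 rose and 9 fell (6 and 10 adjusted over the list alone). Dppa2 stood at 1.18 and Fbxo15 at 1.09. That list's median of -0.04 and mean of 0.03 differed in sign, and camera did not call it (direction down, adjusted p = 0.471).

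The other lists did not pass camera in p400 knockdown, with adjusted p from 0.0982 to 0.766. The members that rose and fell were 4 and 8 of 26 p53 targets, 7 and 1 of 22 ribosome biogenesis genes (Myc 1.52) and 2 and 4 of 17 cholesterol synthesis genes. They were 6 and 1 of 17 mesoderm genes (Snai1 2.07) and 7 and 3 of 14 fibroblast genes that would mark feeder cells. Further counts were 2 and 4 of 21 DNA replication genes, 6 and 3 of 16 neural ectoderm genes, and 9 and 7 of 22 imprinted genes (Magel2 2.33, Igf2 1.85). The last were 4 and 7 of 25 epithelial junction genes, 3 and 4 of 19 genes of the Tip60-p400 complex, and 3 and 1 of 11 housekeeping genes. Of 14 stress response genes, 2 rose and 7 fell. The median was -0.23, the mean was 0.11 with Hspa1a at 4.10, and camera gave the direction as down. Adjusted over the list alone, the counts differed for mesoderm (7 and 1), feeder (8 and 3), DNA replication (2 and 3) and stress response genes (3 and 7).

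The count of 6577 genes was 3150 without p400 replicate 2, 3068 with the arrays scaled to a common spread, and 1775 with a fold change of at least 1.5 required as well. The balance turned to 2882 higher and 6784 lower with the arrays centred on their medians in place of loess, and to 3891 higher and 4286 lower with LogRatio as deposited. The number of lists called was 14 with median centring and 5 among genes well above background in both channels of all arrays.

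The second comparison asks which genes depend on Tip60. Knockdown of Tip60 also raised genes of the 2-cell stage: Zfp352 rose 11.5-fold (log2 3.53 ± 0.10 SE, n = 3 Tip60 and 4 EGFP arrays), and Usp17lb, a deubiquitinase of a multicopy family, rose by 3.47 ± 0.06. Krt23, a type I keratin, rose by 4.26 ± 0.13 (well above background on 2 of 4 EGFP arrays). Its rise ran from 2.38 to 4.32 over the alternatives. The olfactory receptor genes Olfr390 and Olfr120 were at least 5.71-fold and at least 5.17-fold higher. Kat5 itself fell by 1.49 on the log2 scale (± 0.07, 2.80-fold lower, limma adjusted p = 1.36e-05), while Ep400 stood at 0.17 ± 0.06 (adjusted p = 0.0901). Of 26 targets of p53, 13 fell, among them Bbc3, a cell death gene (-0.62), and Gdf15, a secreted stress factor (-0.50, call lost under 5 of 21 alternatives). Camera called this list (adjusted p = 0.000583), though not with an estimated correlation (adjusted p = 0.157).

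Of 16949 genes tested with limma, 4332 passed an adjusted p of 0.05, 2586 higher and 1746 lower in Tip60 knockdown, against 6327 with an unadjusted p under that value. At least 2-fold changes were seen in 619 higher and 7 lower genes, and 62 genes were at least 8-fold higher. Where a gene was not well above background on any array of a group, the bright group's mean was set against the higher of the dim signal and the lowest signal well above background, and the result is given as at least N-fold. By this bound Tdpoz1 was at least 4.61-fold, Olfr983 at least 4.62-fold, Cst7, a cysteine protease inhibitor, at least 4.55-fold and Ecm2, a matrix protein, at least 3.41-fold higher, with limma adjusted p from 4.06e-06 to 0.000335. Spdye4b rose by 3.94 ± 0.12 (well above background on 2 of 4 EGFP arrays) and Olfr20 by 3.55 ± 0.11. The falls were smaller: Asb9 was at least 2.0-fold and Ppnr at least 1.45-fold lower, and Aim2, a sensor of cytosolic DNA, fell by 1.01 (well above background on 1 of 3 Tip60 arrays, call lost under 6 of 20 alternatives). Dtna, a dystrophin-associated protein, stood at -0.99, Bahcc1 at -0.98, the myosin light chain gene Myl9 at -0.97, Igdcc4 at -0.91, the sperm membrane gene Spaca4 at -0.91 and the tubulin polyglutamylase Ttll6 at -0.90, with limma adjusted p from 4.25e-05 to 0.00275. On Tip60 replicate 3, Bahcc1 (1.60), Dtna (-2.42) and Asb9 (-2.50) stood above the EGFP arrays (0.02 to 0.08, -3.21 to -2.96 and -4.95 to -4.32). With that array included these 3 calls were lost (adjusted p = 0.702, 0.283 and 0.633), and with array weights as well Dtna alone kept its call (adjusted p = 0.0394).

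**Figure D3:**
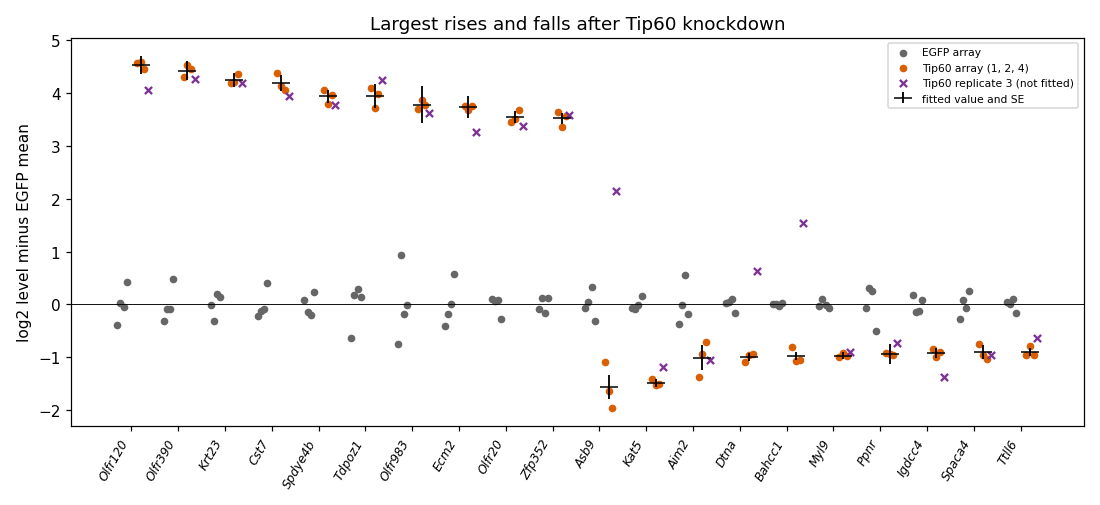
The 10 genes with the largest rise and the 10 with the largest fall in Tip60 knockdown, with the log2 level minus the mean of the EGFP arrays on the vertical axis. Points are EGFP and Tip60 arrays, crosses Tip60 replicate 3, and black ticks the fitted values with standard errors, from 4.54 for Olfr120 to -1.57 for Asb9, which are not bounds.

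All 7 measured genes of the 2-cell-like list rose in Tip60 knockdown (7 adjusted over the list alone, median log2 2.91, camera adjusted p = 2.87e-11, and adjusted p = 0.124 with an estimated correlation). Of 24 germ cell genes, 12 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.000471, and 0.157 as the adjusted p with an estimated correlation). Smc1b, a meiotic cohesin, stood at 1.31 and Dazl at 1.30. Of 17 endoderm genes, 9 rose and none fell (10 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.000471, and adjusted p = 0.124 with an estimated correlation). The fetal serum protein Afp was at least 1.84-fold higher and the chemokine receptor Cxcr4 stood at 1.28 (well above background on 1 of 4 EGFP arrays, call lost under 7 of 20 alternatives). Of 16 Hox genes, 10 rose and none fell (11 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 0.000471, and adjusted p = 0.124 with an estimated correlation). The array held 37 Hox and 23 endoderm genes, and the others were too dim to test. Genes dim in EGFP RNA entered only where bright in Tip60 knockdown, which favours rises. Hoxb2 stood at 1.80 (well above background on 3 of 4 EGFP arrays) and Hoxa10 was at least 2.13-fold higher. Of 16 mesoderm genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.42, camera adjusted p = 0.000620, and adjusted p = 0.124 with an estimated correlation). Snai1, a repressor of epithelial genes, stood at 1.51 and the homeobox gene Evx1 at 1.90 (well above background on 1 of 4 EGFP arrays). Of 17 trophectoderm genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 0.0469, and adjusted p = 0.293 with an estimated correlation). The placental gene Plac1 stood at 1.17 and the T-box factor Eomes at 0.47 (call lost under 6 of 21 alternatives).

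The p53 targets were lower as a list in Tip60 knockdown: 13 of 26 fell and 2 rose (13 and 2 adjusted over the list alone, median -0.24, camera adjusted p = 0.000583, and adjusted p = 0.157 with an estimated correlation). Of 25 epithelial junction genes, 7 fell and none rose (8 and 0 adjusted over the list alone, median -0.08, camera adjusted p = 0.0357, and adjusted p = 0.157 with an estimated correlation). Of the tight junction genes, Cldn4 stood at -0.45 and Marveld2 at -0.32. Epithelial junction and trophectoderm genes each lost their call as a list under 7 of 21 alternatives, Cldn4 under 9 of 21 and Marveld2 under 3 of 21. With the slide as a block, and within slide 2, the same 8 lists were called. Slide 3 held 1 Tip60 array of the fit, too few for a test within it. The median of the 2-cell-like list was 2.87 with the slide as a block and 2.86 within slide 2, and for Hox genes the 2 values were 0.65 and 0.45. Those of germ cell genes were 0.24 and 0.25, and of endoderm genes 0.22 and 0.30. They were 0.41 and 0.32 for mesoderm genes, and for trophectoderm genes 0.23 and 0.27. For p53 targets they were -0.22 and -0.22, and for epithelial junction genes -0.10 and -0.12. Over the 20 settings run for list medians, the median ran from 2.60 to 2.98 for the 2-cell-like list. For germ cell genes it ran from 0.03 to 0.29, for endoderm genes 0.03 to 0.44 and for Hox genes 0.11 to 1.02. It ran from 0.13 to 0.52 for mesoderm, 0.06 to 0.38 for trophectoderm, -0.45 to -0.20 for p53 and -0.29 to -0.07 for epithelial junction genes. The highest medians of Hox and mesoderm genes came from within slide 3, with its 1 Tip60 array.

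Among the same 5 pluripotency genes, Klf4 fell by 0.48 in Tip60 knockdown (± 0.06, limma adjusted p = 0.00155) and Sox2 fell by 0.21 (± 0.05, adjusted p = 0.0197). Sox2 missed the threshold under 9 of 21 alternatives and Klf4 under 2 of 21. Pou5f1 stood at 0.06 ± 0.06 (adjusted p = 0.505), Nanog at 0.00 ± 0.06 (adjusted p = 0.983) and Zfp42 at -0.03 ± 0.11 (adjusted p = 0.863). Of 27 pluripotency genes, 4 rose and 4 fell, with Fbxo15 at 0.65 and Dppa2 at 0.55. The remaining lists did not pass camera, with adjusted p from 0.266 to 0.845. The members that rose and fell were 0 and 0 of 20 mitosis genes, 2 and 4 of 14 stress response genes (Hspa1a 2.44), and 1 and 1 of 21 DNA replication genes. They were 4 and 3 of 16 interferon response genes (Mx2 at least 2.46-fold higher, Bst2 -0.62), 5 and 2 of 14 feeder fibroblast genes, and 0 and 1 of 17 cholesterol synthesis genes. Further counts were 0 and 0 of 11 housekeeping genes, and 0 and 1 of 19 genes of the Tip60-p400 complex, the 1 being Kat5. The last were 0 and 0 of 22 ribosome biogenesis genes, 5 and 7 of 22 imprinted genes (Magel2 1.40, Phlda2 -0.75, Meg3 -0.67), 2 and 2 of 14 neural ectoderm genes, and 3 and 2 of 20 glycolysis and hypoxia genes. Adjusted over the list alone, the counts differed for stress response (2 and 5), DNA replication (1 and 0), feeder (5 and 4), cholesterol (0 and 0), imprinted (6 and 8) and neural ectoderm genes (3 and 4). Median and mean differed in sign for stress response (-0.13 and 0.05), glycolysis (-0.04 and 0.03) and ribosome biogenesis genes (-0.01 and 0.00). Camera gave the direction as down for imprinted and neural ectoderm genes, whose medians were 0.07 and 0.10.

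**Figure D4:**
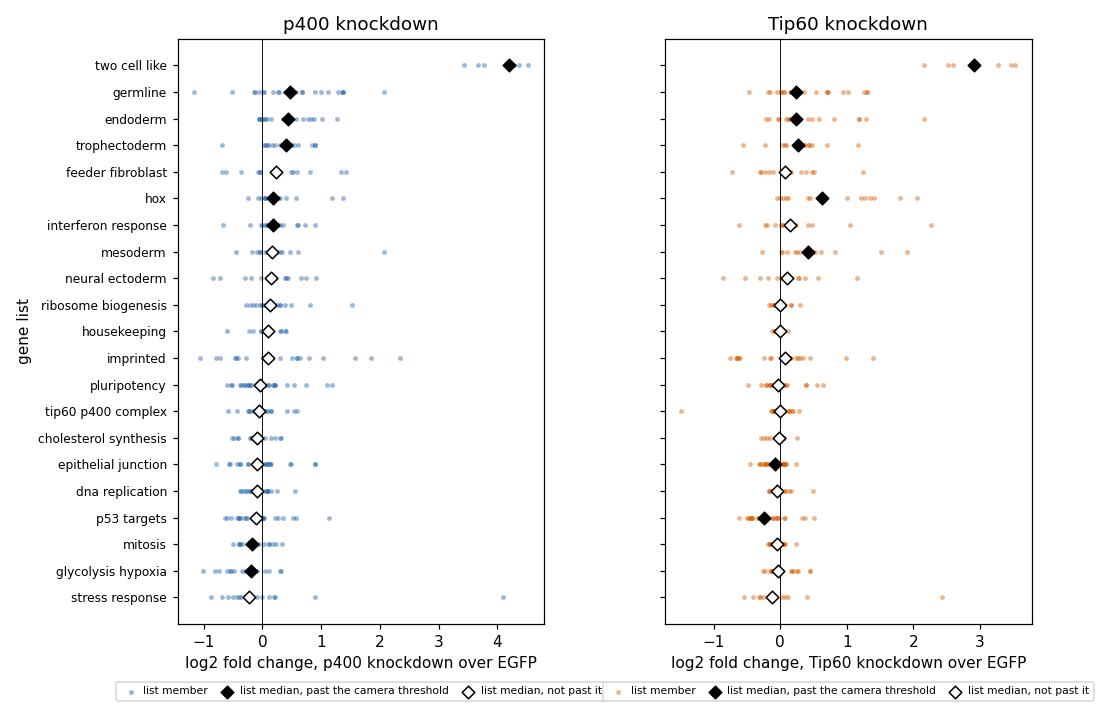
Median log2 fold change of the members of each of the 21 gene lists in p400 and in Tip60 knockdown, on the horizontal axes, with members as points and medians as diamonds, filled where camera called the list. The 2-cell-like list stands at 4.20 in p400 and 2.91 in Tip60 knockdown, above every other list.

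The count of 4332 genes was 4820 with the slide as a block and 1880 within slide 2. It was 1420 with a fold change of at least 1.5 required as well. The balance turned to 2097 higher and 2344 lower with quantile normalization and to 1452 higher and 4916 lower with median centring. The number of lists called was 5 among genes well above background on all arrays.

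The third comparison asks how far the effects of the 2 knockdowns are shared. The largest shared rises were in Zfp352 (log2 4.52 in p400 and 3.53 in Tip60 knockdown), Sp110 (3.68 and 3.48), Usp17lb (3.42 and 3.47), Ankrd22 (3.47 and 3.40) and Spdye4b (3.42 and 3.94). The largest shared falls were in Igdcc4 (-1.15 and -0.91), St8sia1 (-1.25 and -0.84), Nkx6-3 (-1.22 and -0.84), the long non-coding RNA Firre (-0.99 and -0.83) and Efs (-1.33 and -0.80). Of 16851 genes tested in both, 1786 were higher in both and 967 lower in both, while 50 were called in opposite directions. Independent calls would give 551 genes higher and 286 lower in both. Fisher's exact test, one-sided, gave a log10 p of -746 for the genes higher and -354 for those lower. The test takes genes as independent, which they are not, so these p values overstate the evidence. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.696 and a Spearman rho of 0.623, the only pair of comparisons correlated. The 2753 genes shared in direction became 1787 without p400 replicate 2, and were 2962 with the slide as a block in the Tip60 fit. The labels do not say whether the EGFP RNA of both experiments came from the same cultures.

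**Figure D5:**
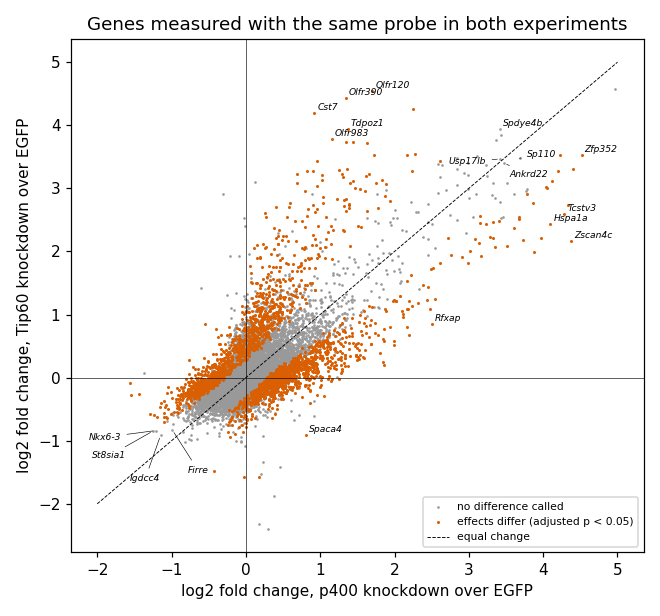
Log2 fold change in p400 knockdown on the horizontal axis against that in Tip60 knockdown on the vertical axis, 1 point per gene measured with the same probe in both. Genes whose effects differ are coloured and named genes are labelled, with Zfp352 at 4.52 and 3.53.

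The difference between the 2 effects was tested for 16425 genes measured with the same probe. Zscan4c rose more in p400 than in Tip60 knockdown, by a log2 difference of 2.22 ± 0.30 (4.37 against 2.16), as did Tcstv3 (1.69 ± 0.24), Hspa1a (1.66 ± 0.12) and Rfxap, a regulator of MHC class II genes (1.65 ± 0.16). Spaca4 rose by 0.81 in p400 knockdown and fell by 0.91 in Tip60 knockdown, a difference of 1.71 ± 0.16. Differences the other way were called for Cst7, Olfr390, Olfr120, Olfr983 and Tdpoz1. None of these 5 was well above background on any single-colour EGFP array, so their differences have no size or rank. With the offset of the p400 background correction at 0 the 5 differences kept their sign, with adjusted p from 0.0227 to 0.0625 in the test of the difference on limma's standard errors, and Olfr120 and Olfr983 lost their call. With Agilent's processed signals, which changed the signal and the background step as well, the sign turned (adjusted p from 0.137 to 0.804), so the calls rest on how signal and background were processed. In all, 2416 genes passed, 1167 with the p400 effect above and 1249 below that of Tip60, against 4919 with an unadjusted p under 0.05. The p400 effect was above in 1508 and below in 868 with quantile normalization of the Tip60 arrays, and in 1130 and 569 with normexp on them. It was above in 1707 and below in 1085 with processed p400 signals, and in 1311 and 1699 with LogRatio as deposited. The count was 683 with the smaller degrees of freedom of the 2 fits, 1315 with the offset at 0 (725 above and 590 below), 1434 without p400 replicate 2 and 1600 without p400 replicate 4. All 10 genes named kept an adjusted p between 0.0213 and 0.0326 with the smaller degrees of freedom. The array format went with the knockdown, so the 2 cannot be told apart in this comparison.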

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

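The tests of gene copies, of normalization and slide, of a common scale factor, of a wrong label, and of the offset and the background correction were chosen after the results were seen.

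The 7 measured genes of the 2-cell-like list rose in both knockdowns. Arg2 and Zfp352 were assumed, without a check of sequences, to have no near-identical copies. Their lowest log2 fold change over both comparisons was 2.91, but these rises were known when the test was chosen. Binding of related transcripts therefore stays open as a source for these genes. For Zscan4c, Tcstv1, Tcstv3, Usp17la and Usp17lb it also stays open. The largest difference within the Tcstv or Usp17l pair was 0.78 in either comparison, so a probe may read several copies. Normalization or slide is argued against by the list's lowest median over 14 p400 and 20 Tip60 settings, 2.60. Binding of related transcripts leaves open which copies rose, since the probes' signal was higher in knockdown than in EGFP RNA either way. A change in the cells after loss of either protein remains a hypothesis that was not tested.

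The effects of the 2 knockdowns differed for 2416 genes. The p400 minus Tip60 difference was 2.22 for Zscan4c, 1.71 for Spaca4, 1.69 for Tcstv3, 1.66 for Hspa1a and 1.65 for Rfxap. It was -3.27 for Cst7, -3.08 for Olfr390, -2.84 for Olfr120, -2.63 for Olfr983 and -2.57 for Tdpoz1, fitted values that are not sizes, since none of these 5 was well above background on any single-colour EGFP array. Of the genes that differed, 856 were higher in Tip60 than in p400 knockdown with a Tip60 log2 fold change above 0. The test of the difference has no count over other splits of the arrays.

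For the 856 genes higher in Tip60 knockdown, the offset of the p400 background correction is argued against as the whole cause by a median difference over 855 genes that kept 87.1% of its main value with the offset at 0 (-0.54 against -0.62). Then 360 genes still differed the same way and 495 lost their call, with a median SE of 0.16 against 0.13. The signal and background correction as a whole stays open: with Agilent's processed signals the median difference kept 64.4%, while 359 genes still differed the same way, 496 lost their call and 174 turned sign. For Cst7, Olfr390, Olfr120, Olfr983 and Tdpoz1, which lie near the floor, both stay open, with a lowest difference of -1.99 with the offset at 0 and of 0.13 with processed signals. A common scale factor between array formats is argued against by genes called in both the same way that differ, of which 42.1% lay on the smaller side (302 larger in Tip60 and 415 in p400), but the knockdown and the array format cannot be told apart.

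Tip60 replicate 3, which entered only in alternatives, had a 2-cell-like list median of 2.57 over EGFP, where the EGFP arrays reached 0.07, and Kat5 at -1.19 over EGFP. Its Hox median was 0.10, where the EGFP arrays reached 0.11 and the other Tip60 arrays had 0.52 to 0.92, and its interferon response median was -0.06 against 0.09 to 0.15. The Kat5 value of -1.19 argues against an EGFP sample under the wrong label. Lower signal over background on that array is consistent with a correlation of its fold changes with the other Tip60 arrays of 0.796 among the brightest of 3 equal groups of genes, where the other arrays had 0.396 to 0.748. In the dimmest group it was 0.584 against 0.801 to 0.878 for the others. No biological explanation was tested.

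Single arrays far from the others of their group were found in 9 of 179 tests, where chance gives about 1 in 20, or 8.95. Replicate 4 of p400 had log2 ratios of 2.99 for Clec10a (others 4.23 to 4.48), 0.81 for Olfr120 (others 1.96 to 2.05) and 0.46 for Olfr983 (others 1.37 to 1.40). Krt23 stood at -1.25 in Tip60 replicate 4 (others -1.44 to -1.41). In EGFP controls, Tdpoz1 stood at -8.05 in replicate 1 (others -7.27 to -7.13), Olfr20 at -5.03 in replicate 4 (others -4.69 to -4.65) and Meg3 at 4.07 in replicate 4 (others 4.18 to 4.19). In Tip60 replicate 3, Dtna stood at -2.42 (others -4.14 to -3.99) and Bahcc1 at 1.60 (others -1.01 to -0.75).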

How the results depend on the processing

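Agilent's processed p400 signals and the offset at 0 in the comparison of both knockdowns, the slide as a block there, and the smaller degrees of freedom were added after seeing the data. Every alternative named was run. Where a value moved, the cause was not tested unless named.

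The number of p400 genes, 6577, was 3068 with scaling between arrays and 1775 with a fold change of at least 1.5, which is narrower by construction, and between 5890 and 9666 in the other settings. Leaving out 1 replicate gave 3150 (without p400 replicate 2) to 5752. Of the calls 57.3% were higher, 73.2% with scaling and 29.8% with median centring, which moved the median of all genes to -0.11. The number of Tip60 genes, 4332, was 1880 within slide 2, 1877 within slide 3 (1 Tip60 array, so no reading of stability), 1420 at 1.5-fold or more, and between 2935 and 6368 in other settings but the replicate block. Leaving out 1 replicate gave 3151 to 3696. The higher calls were 59.7%, 47.2% with quantile normalization and 22.8% with median centring, which moved the median to -0.20, and 72.2% with no filter.

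The 8 lists called in p400 knockdown became 14 with median centring, 5 with the strict filter, 0 with an estimated correlation and 0 with fry, and 6 to 9 leaving out 1 replicate. The 8 lists called in Tip60 knockdown became 5 with the strict filter, 0 with an estimated correlation (6 at an unadjusted p under 0.05; fry called 11), and 6 to 8 leaving out 1 replicate. Genes shared in direction, 2753, were 1787 (without p400 replicate 2) to 2453 leaving out 1 replicate. Genes that differed, 2416, were 683 with the smaller degrees of freedom, 1315 with the offset at 0 and 1434 (without p400 replicate 2) to 2732 leaving out 1 replicate.

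With the replicate number as a block, the Tip60 count was 1864, the shared genes 1380 and the genes that differed 1556. Same-numbered samples had correlations of -0.286, -0.376 and -0.120, and 0 of 3 correlated best with their own number. No same-numbered samples shared a slide, and the slide could hide a pairing. Whether the numbers pair the samples therefore stays open.

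Among named genes called in either setting, direction turned for Ccne1 (-0.10), Cdc20 (-0.015) and Sqle (-0.00043) in p400 knockdown with median centring, and for Tagln (0.25) in Tip60 knockdown in the series matrix; the cause was not tested. Other settings kept 1055 gene values in p400 and 1085 in Tip60 on their side of the threshold, with 66 and 148 weaker and 3 and 20 stronger, and lists did so in 200 and 275 cases, with 22 and 15 weaker and 9 and 4 stronger. Leaving out a replicate weakened 36 and 64 gene values and 4 and 6 list values. Signal over background limits the dim genes, whose folds are given as bounds only where no array of a group was well above background.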

Other observations

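The count of splits that keep the slides, and the alternatives with other p400 signals or offset, were chosen after the results were seen.

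Gene families were defined by symbol stem. Of 419 families with at least 5 members among genes measured in both experiments, 3 were over-represented among the 1750 genes higher in both (Fisher's exact test, one-sided, adjusted over families). Of 8 Pramel genes, which lie in clusters and are expressed in germ cells and early embryos, 7 were higher in both (adjusted p = 0.000469), with median log2 fold changes of 1.89 in p400 and 2.54 in Tip60 knockdown. Of 7 Defa genes, which encode intestinal defensins, 6 were higher in both (adjusted p = 0.00194), and of 11 Krtap genes, which encode hair keratin-associated proteins, 7 were (adjusted p = 0.00482). Of 298 Zfp genes, which encode zinc finger proteins, 34 were lower in both (adjusted p = 0.0446). A gene dim in EGFP RNA was measured only where knockdown RNA was well above background, which favours rises in families dim in control cells. The shares and Fisher p values of the 3 families may therefore be too favourable. Copies within a family may also share transcripts on 1 probe. The 3 families that were higher are thus a hypothesis about clustered multicopy genes, not a count of independent genes.

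A second hypothesis was that genes nearly silent in control cells rise under both knockdowns. With the genes in 4 equal groups by control level, the median log2 fold change of the lowest group minus that of the highest was 0.30 in Tip60 knockdown but 0.040 in p400 knockdown. The p400 value was 0.07 with the offset at 0, and 0.09 with Agilent's processed signals, which also changed the background step. All 3 lie under the 0.1 set beforehand, so the prediction was not met for both knockdowns. A value under 0.05 was set as the bound against the hypothesis, which 0.040 met and 0.07 and 0.09 did not. The groups held only genes that passed the filter on dim probes. A gene dim in EGFP RNA entered only where bright in knockdown RNA, which favours rises in the lowest group. The test therefore cannot decide the hypothesis for genes nearly silent in control cells. In p400 knockdown the lowest group had 922 genes called higher and 294 lower, and the highest group 742 and 737.

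Other splits of the arrays show which counts chance could give. For Tip60, 1 of the 35 splits of the 7 arrays gave as many genes as the 4332 found, the real one. The highest other gave 181, and it followed the slides, while the count with the slide as a block was 4820. The 35 splits ignore the slides, so they do not exclude chance. Of these splits 18 keep the real division over the slides, too few for a share under 0.05: 1 gave as many genes and the highest other gave 0. Of the 35 splits, 1 gave as many shared genes as the 2753 found and the highest other gave 3, which adds nothing, since no other split called enough genes to share as many. For the number of Tip60 lists called, 3 of 35 splits gave as many as the 8 found, the highest other also 8, so chance cannot be excluded for that number, though both other splits kept the 3 Tip60 arrays together. The 2-cell-like list had a camera adjusted p of 2.87e-11 in the real split and 0.000235 at the smallest in the others, 11 of which called it. Endoderm genes too had their smallest p in the real split. With the real split counted, 2 splits gave as small a camera p for each of germ cell, mesoderm, p53 and epithelial junction genes. As small a p came in 3 splits for Hox and 7 for trophectoderm genes. For p400 the 7 assignments of the knockdown to the channels are too few to give a share under 0.05: 1 gave as many genes as the 6577 found and the highest other gave 0, and 3 gave as many lists as the 8 found, with a highest other of 11.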
